A study of Homo sapiens with 20 samples.

How the data were processed

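RNA from 20 healthy human kidney samples was measured by RNA sequencing. The tissue was kept in RNAlater, a solution that stops RNA decay, and dissected by hand under a microscope into glomeruli, the filtering units of the kidney, and tubules, the segments that process the filtrate, per the labels' protocols. Per the same protocols, RNA entered library preparation with a RIN (RNA integrity number) over 7 and at least 100 ng, libraries were polyA-selected without strand information with the TruSeq kit, and the median depth was 35000000 single-end reads of 100 bp. CASAVA 1.8.2, FastQC, Trim Galore and STAR 2.4.1d, with the human builds hg19 and GRCh37, are named per the submitters' processing notes. The counting tool, the annotation, any gene filter and the normalization are not given in the sources used here.

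Each deposited file held 1 expression signal per gene for 33606 Ensembl gene IDs, and the authors deposited these values without a header or a stated unit. The values had been brought to a common distribution across samples. The sorted values of the 20 samples differed by at most 0.0949% over the 10000 highest ranks, the maximum was 49645.9 in each sample, and the totals lay between 495293 and 495318. This is the pattern that quantile normalization leaves, and the step is inferred from the values. A value therefore gives a gene's place among the genes of its sample on a shared scale, several abundant genes take exactly the same values, and a true difference in total RNA is not in the values. Across 15822 protein-coding genes the median value had a Spearman correlation of -0.0195 with exonic length, a correlation across genes, which are not independent replicates. Whether the values were RPKM, FPKM or another unit before that step is not given in the sources used here. The depth of each sample is unknown and counts were not recovered, so no counting interval is given.

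Symbols were found for 32460 of the 33606 IDs in a gene name table, older symbols were matched through RefSeq synonyms, and positions were taken from GENCODE version 44 lifted to build 37. Before the data were examined, 30 gene lists were fixed, 16 of them markers of cell types, along with the tests, the alternatives and the rule for named genes. Of 278 list entries, 270 were matched. PECAM1, CD68, KRT5, CYP11B1, STAR, ADIPOQ and CFB are among those not analysed here. A list score was the mean over the list's genes of log2(value + 1), so fold ranges are on that scale and understate the range of low genes.

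All samples carry the same tissue and disease labels and form 1 group. The labels do not tie a sample or a column to glomeruli or tubules, so the planned comparison of both compartments was not made, and samples were never sorted by their values. Nothing in the labels says that the samples came from separate donors. The permutation p-values treat the samples as interchangeable, so they can be too small if some samples share a donor. They describe these samples only. The labels name no sequencing batch, and no within-batch values could be given. Genotypes are not analysed here.

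Relations between list scores were tested with Pearson's r and Spearman's rho, each with a 2-sided permutation test of 100000 resamples (smallest p 1e-05). The family was the podocyte list against the other 29 lists and the proximal tubule list against 28, which makes 57 pairs, with Benjamini-Hochberg adjustment and shared genes left out. Each r was computed again without the 2 samples farthest from the median of the first list. A pooled r was given unless the scores of either list had a gap of over 40% of their range with at least 3 samples on each side, which no list had. Pairs were called on the adjusted p of Pearson's r, a choice made after part of the rank correlations had been seen, so the number called by both measures is also given. Counting the lists with a range over 1 log2 unit was also chosen after the values were seen.

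Variable genes were ranked by the SD of log2(value + 1) minus a lowess trend on the mean (fraction 0.3), among 11931 genes with a symbol and a median of at least 1. Each list was tested among the top 500 with a one-sided Fisher's exact test and Benjamini-Hochberg adjustment. Genes are not independent replicates, so this test describes the lists and is not a test across samples. Named genes were the 2 members of each list with the highest median, the member with the largest SD among those with a median of at least 1, the 10 genes highest in median and the 15 most variable genes. Genes that can show a donor's sex or genotype were left out, as were IDs without a symbol. Pseudogenes and mitochondrial genes were passed over among the 15, a choice made after seeing the data, and 3 were passed over. Some genes that the rule takes are not reported here by name. Other genes named below were chosen after their values were seen.

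On simulated data with 11931 genes, the top 500 held 98% of 200 genes whose SD was multiplied by 2 and 100% of those multiplied by 3. All other simulated genes lay on the trend, unlike real genes, so these shares do not give the recovery in the real data. In simulations of 20 samples, the unadjusted p was under 0.05 in 2.5% of 200 draws with a true r of 0, in 71% at 0.5 and in 93.5% at 0.7. Pairs of lists were called on an adjusted p, which is a stricter rule. The shares at 0.5 and 0.7 thus overstate the recovery under that rule, which they do not give. The alternatives were a pseudocount of 0.1, scaling by the median ratio over genes, list medians, z-scores, leaving out low members, other numbers of top genes, other filters and no trend correction. Leaving out each sample in turn and testing all 435 pairs of lists were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.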

Results

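The samples were 20 healthy human kidney samples of 1 group, numbered 1 to 20. The study set out to relate genotype to gene expression in the glomeruli and tubules of the kidney and to link this to loci of kidney disease. The expression side is described here over all samples, since the labels give no compartment per sample. Between 23575 and 25737 genes had a value above 0 in a sample, with a median of 24349. Between 12267 and 12268 genes had a value of at least 1, a number that the common distribution of values fixes.

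Transcripts of the mitochondrial genome, which encode parts of the respiratory chain, took most of the signal in each sample. The 10 genes highest in median were all mitochondrial, led by MT-CO3 (median 49645.9, range 32971.9 to 49645.9) and MT-CO1 (38488.9, 28583.2 to 49645.9). They were followed by MT-CO2, MT-ND4, MT-ATP6, MT-CYB, MT-ND3, MT-ND1, the ribosomal RNA gene MT-RNR2 and MT-ND2. These 10 genes took a median of 53.2% of the total (range 50.8% to 53.5%), and all mitochondrial genes took 61.0% (58.4% to 62.0%). The highest nuclear genes included GPX3, a secreted glutathione peroxidase (7631, 1842 to 12452), and FTL, the ferritin light chain (5145, 3590 to 13631). Values this high are ranks placed on a shared scale, so their spread between samples is limited by the normalization.

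Genes of the proximal tubule, thick ascending limb and principal cells scored above those of podocytes. The proximal tubule list, genes of the segment that takes back most of the filtrate, had a median score of 6.82 (range 5.58 to 7.37, SD 0.51, n = 20). The podocyte list, genes of the cells that form the filtration barrier, had 2.83 (0.91 to 3.61, SD 0.68, n = 20). Markers of both were thus present in the same samples at different levels. The thick ascending limb list scored 5.46 (4.23 to 7.21), the principal cell list of the collecting duct 5.32 (4.61 to 6.24), the intercalated cell list 3.70 (2.56 to 4.52) and the distal convoluted and connecting tubule list 3.37 (1.09 to 4.07).

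Podocyte genes ranged widely. PODXL, the surface sialomucin podocalyxin (chromosome 7, 131185021 to 131242976, GRCh37), had a median of 34.5 and ranged from 8.25 to 75.3. Of the 11 podocyte genes, 10 had a highest value over 5 times the lowest. The lowest podocyte score, 0.91, was that of sample 3, which held the lowest value of 9 of the 11 genes. Without it 8 of the 11 were over 5 times, and the fold range of the score fell from 6.51 to 3.02 (2.02 to 3.61). Sample 3 also had the lowest value of all 7 distal convoluted tubule genes, and the fold range of that score fell from 7.87 to 3.74 without it (2.17 to 4.07). In the proximal tubule list, MIOX, the inositol-degrading oxygenase, had a median of 558 (range 97.0 to 881), and FABP1, a fatty acid carrier, had the largest SD (90.4, 15.9 to 986). UMOD, which encodes uromodulin of the thick ascending limb (chromosome 16, 20344373 to 20367623), had a median of 1363 and ranged from 245 to 7631, and SLC12A1, the sodium-potassium-chloride cotransporter NKCC2 (chromosome 15, 48470635 to 48596275), ranged from 20.6 to 535 around 71.9.

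In the distal convoluted tubule, SLC12A3, the thiazide-sensitive cotransporter (chromosome 16, 56899119 to 56949762), had a median of 65.3 and ranged from 0.417 to 144, and CALB1, a calcium-binding protein, had 49.4 (3.90 to 139). AQP2, the water channel of principal cells, had a median of 230.3 (114 to 927), HSD11B2, which inactivates cortisol, had 152 (88.8 to 307) and SCNN1G, a subunit of the epithelial sodium channel, had 24.9 (7.55 to 53.3). ATP6V1B1 and ATP6V0D2, proton pump subunits of intercalated cells, had medians of 34.6 and 21.0, and the anion exchanger gene SLC4A9 had 9.96 (1.99 to 24.4).

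**Figure D1:**
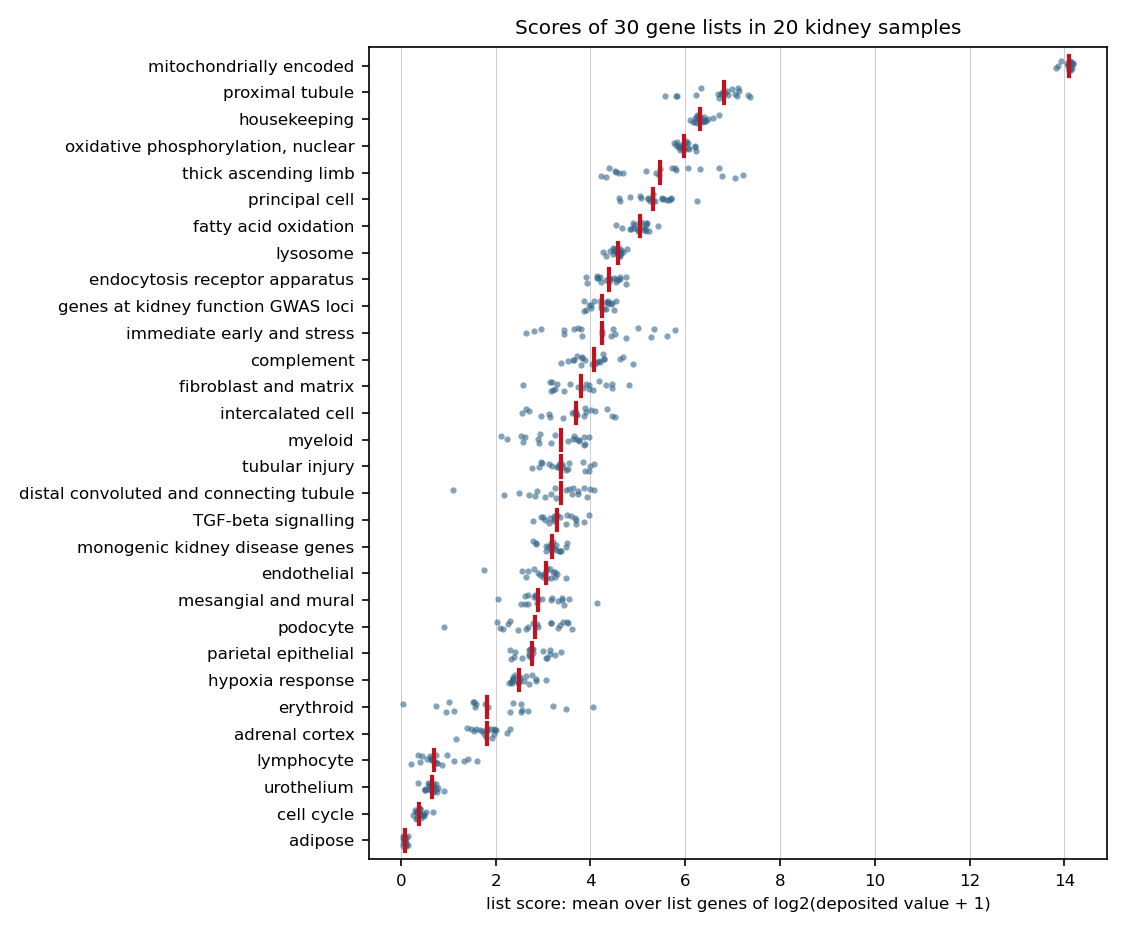
Scores of 30 gene lists, as the mean of log2(value + 1) over the list's genes, on the horizontal axis in 20 kidney samples (points, spread vertically at random for view), with the median as a red line. The proximal tubule list has a median of 6.82 and the podocyte list 2.83, and 1 sample lies at 0.91 in the podocyte list.

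Genes from lists of cells outside the tubule were also present. The endothelial list scored 3.06 (1.75 to 3.49, and 2.56 to 3.49 without sample 20), with PLVAP at 37.4 and EMCN at 13.3, and SOST had the largest SD (3.15, 0.0273 to 10.1). The mesangial and mural list, cells that hold and contract around small vessels, scored 2.88 (2.04 to 4.14, and 2.04 to 3.54 without sample 2), with TAGLN at 26.2 and ACTA2 at 18.7. The parietal epithelial list of Bowman's capsule scored 2.76 (2.31 to 3.38), with VCAM1 at 15.0 and KRT7 at 13.0. The fibroblast and matrix list scored 3.79 (2.59 to 4.81), with MGP at 43.5, LUM at 31.7 and COL3A1 between 3.83 and 39.1. The myeloid list scored 3.39 (2.11 to 3.96), with the complement genes C1QA at 25.7 and C1QB at 16.3 and the neutrophil gene S100A9 between 1.63 and 54.1.

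Lymphocyte genes were low, with a score of 0.70 (SD 0.36), and 2 of 9 had a median of at least 1, PTPRC at 1.14 and NKG7 at 1.02. The erythroid list had the widest range, from 0.05 in sample 10 (0.74 without it) to 4.06 in sample 16, with HBB between 0.117 and 179.5 and HBA2 between 0 and 20.8. HBA1 and HBA2 are near-identical copies, so their split is uncertain. The urothelium list scored 0.65 and the adipose list 0.08. UPK1B, at 4.45, was the 1 urothelial gene with a median of at least 1, and UPK1A was at 0.0466. PLIN1 and CIDEC, the highest adipose genes, were at 0.164 and 0.0120. The adrenal cortex list scored 1.81 (1.17 to 2.30), of which CYP17A1 (23.1, 6.39 to 71.3) was the 1 gene with a median of at least 1, and HSD3B2 was at 0.430.

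The immediate early and stress list, genes that respond within minutes to a stimulus, had a median score of 4.24 and ranged from 2.65 in sample 8 to 5.79 in sample 12. FOSB ranged from 0.271 to 102 around 3.92, while DUSP1 (110, 30.9 to 241) and ZFP36 (74.2, 20.8 to 312) had the highest medians. The tubular injury list scored 3.38 (2.76 to 4.07), with SPP1, osteopontin, at 748 (356 to 6363) and KRT18 at 20.7. The hypoxia response list scored 2.49 (2.28 to 3.06), with NDRG1 at 72.3, BNIP3 at 36.7 and ANGPTL4 between 0.795 and 39.3.

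Core metabolic lists had score ranges between 0.37 and 0.89 log2 units. The lysosome list scored 4.58 with a range of 0.51, and CTSB (209, 124 to 323) and CTSD (178, 98.6 to 328) were its highest genes. The housekeeping list scored 6.31 with a range of 0.61, led by ACTB (417, 282 to 986) and B2M (326). The nuclear oxidative phosphorylation list scored 5.97 with a range of 0.45, with ATP5F1B at 494, NDUFA1 at 168 and NDUFB8 between 2.92 and 9.35. The mitochondrially encoded list scored 14.11 with a range of 0.37, and MT-ND4L had its largest SD (13631, 4234 to 18370). The fatty acid oxidation list scored 5.04 (4.53 to 5.42), with ACADVL at 105, HADHA at 74.7 and ACADM between 31.0 and 119.5. The cell cycle list scored 0.39, with CCNB1 at 1.38 and CDK1 at 0.464. Of the 30 lists, 18 had a range over 1 log2 unit, and 17 without sample 2, 11, 13 or 20.

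Genes near loci of kidney function were present at very different levels. UMOD and GATM, which makes the creatine precursor (408, 99.8 to 667), had the highest medians of this list, whose score was 4.25 (3.86 to 4.54). DAB2, an endocytic adaptor (chromosome 5, 39371777 to 39462402), had a median of 55.2 and ranged from 30.3 to 71.0, and MANBA, the lysosomal beta-mannosidase (chromosome 4, 103551927 to 103682151), had 2.57 and ranged from 2.12 to 3.67. DAB2 and MANBA were chosen after their values were seen. The endocytosis receptor list scored 4.39 (3.90 to 4.74), with AMN at 64.3 and CUBN, cubilin, at 61.5 (27.1 to 104). The TGF-beta list scored 3.29 (2.79 to 3.96), with DAB2 at 55.2 and TGFBR2 at 36.3. The complement list scored 4.07 (3.39 to 4.89), with C7 at 132 and CD59 at 83.9. The monogenic kidney disease list scored 3.19 (2.79 to 3.52), with SLC3A1 at 64.7, ACTN4 at 62.6 and MUC1 between 31.5 and 106.

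**Figure D2:**
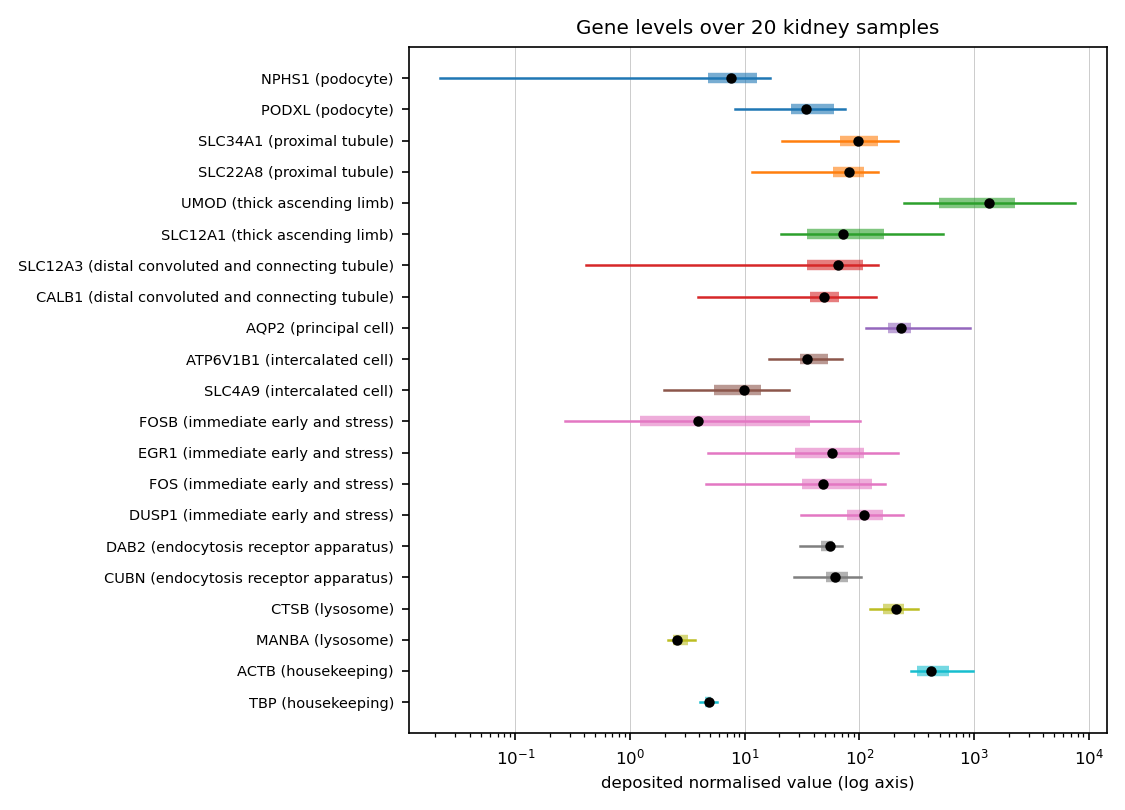
Deposited normalised values of selected genes over 20 kidney samples on a log axis, with the median as a black point, the quartiles as a thick bar and the full range as a thin line, coloured by gene list. FOSB runs from 0.271 to 102 while MANBA runs from 2.12 to 3.67.

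Podocyte and proximal tubule scores rose and fell together across the samples. Their Pearson r was 0.70 (permutation p = 4.8e-04, adjusted p = 0.00684 over 57 pairs) and their rho 0.65 (permutation p = 0.00262, adjusted p = 0.0314 over 57 pairs), and r was 0.53 without the 2 farthest samples (permutation p = 0.0222). All 15 proximal tubule genes had a positive rho with the podocyte score, as had all 7 distal convoluted tubule genes and all 8 intercalated cell genes. All 7 thick ascending limb genes had a negative one, but the list's relation with podocytes did not pass the test (r = -0.47, permutation p = 0.0351, adjusted p = 0.119 over 57 pairs; rho = -0.40, permutation p = 0.0851, adjusted p = 0.188). Of the 57 pairs tested, 12 were called, 7 positive and 5 negative, 18 had an unadjusted p under 0.05, and 8 were called by both r and rho.

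The podocyte score also rose with the distal convoluted tubule score (r = 0.78, permutation p = 1.2e-04, adjusted p = 0.00541 over 57 pairs; rho = 0.62, permutation p = 0.00386, adjusted p = 0.0314). Without the 2 farthest samples r was 0.57 (permutation p = 0.0140), and without sample 3 alone it was 0.60 with an adjusted p of 0.0565 over 57 pairs by permutation, which ended the call. Relations of the podocyte score with the intercalated cell list (r = 0.60, permutation p = 0.00508, adjusted p = 0.0362 over 57 pairs; rho = 0.57, permutation p = 0.00945, adjusted p = 0.0538) and with the list of genes at kidney function loci (r = 0.58, permutation p = 0.00710, adjusted p = 0.0405; rho = 0.57, permutation p = 0.00928, adjusted p = 0.0538) were close to the threshold. Without the 2 farthest samples r was 0.45 (permutation p = 0.0629) and 0.41 (permutation p = 0.0921). The list of kidney function loci shares 4 genes with the proximal tubule list, and these were kept in its pair with podocytes. That pair can thus partly restate the relation of podocytes with the proximal tubule. The intercalated cell call was also lost without sample 3, 4, 15 or 17 alone (r to 0.49), and the call with kidney function loci without sample 1, 2, 3, 4, 6, 8, 15, 17 or 18 (r to 0.50).

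The proximal tubule score rose with the lysosome, distal convoluted tubule and intercalated cell scores. For the lysosome list r was 0.77 (permutation p = 1.9e-04, adjusted p = 0.00541 over 57 pairs) and rho 0.69 (permutation p = 0.00116, adjusted p = 0.0314), and r was 0.66 without the 2 farthest samples. Of 12 lysosome genes, CTSB among them, 10 had a positive rho with the proximal tubule score and 2 a negative one. For the distal convoluted tubule list r was 0.74 (permutation p = 3.8e-04, adjusted p = 0.00684 over 57 pairs), rho was 0.62 (permutation p = 0.00449, adjusted p = 0.0320) and r was 0.77 without the 2 farthest samples. For intercalated cells r was 0.68 (permutation p = 0.00104, adjusted p = 0.00988 over 57 pairs), rho was 0.66 (permutation p = 0.00192, adjusted p = 0.0314) and r was 0.64 without the 2 farthest samples.

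The proximal tubule score fell where thick ascending limb, principal cell, fibroblast, myeloid and housekeeping scores rose. Values are places on a shared scale, so a fall of some genes moves others up. Opposite movement can be partly built in for that reason, which was not tested. For the thick ascending limb r was -0.69 (permutation p = 6.7e-04, adjusted p = 0.00764 over 57 pairs), rho was -0.52 (permutation p = 0.0214, adjusted p = 0.0871) and r was -0.49 without the 2 farthest samples. Without sample 4 this r was -0.60 with an adjusted permutation p of 0.0524 over 57 pairs. For principal cells r was -0.58 (permutation p = 0.00825, adjusted p = 0.0421 over 57 pairs), rho was -0.48 (permutation p = 0.0324, adjusted p = 0.115) and r was -0.47 without the 2 farthest samples. For fibroblasts r was -0.59 (permutation p = 0.00578, adjusted p = 0.0366 over 57 pairs), rho was -0.63 (permutation p = 0.00331, adjusted p = 0.0314) and r was -0.47 without the 2 farthest samples. For the myeloid list r was -0.57 (permutation p = 0.00886, adjusted p = 0.0421 over 57 pairs), rho was -0.64 (permutation p = 0.00309, adjusted p = 0.0314) and r was -0.71 without the 2 farthest samples. For the housekeeping list, of which 6 of 8 genes had a negative rho, r was -0.62 (permutation p = 0.00365, adjusted p = 0.0297 over 57 pairs), rho was -0.68 (permutation p = 0.00128, adjusted p = 0.0314) and r was -0.54 without the 2 farthest samples. All 7 thick ascending limb genes and all 9 fibroblast genes had a negative rho with the proximal tubule score, as had 9 of 10 myeloid genes. Principal cell genes went both ways, with 5 of 7 negative and a median rho of -0.077. The lowest rho were those of FXYD4 (-0.92), AQP3 (-0.71) and AQP2 (-0.67), and the highest that of HSD11B2 (0.22), with no test per gene. The myeloid call was lost under 15 of 25 alternatives, among them leaving out sample 1, 2, 3, 4, 6, 8, 9, 11, 13, 15, 17 or 18 (r to -0.51). The principal cell call was lost under 11, among them leaving out sample 1, 2, 3, 4, 6, 13, 17 or 18 (r to -0.40, without sample 4). The fibroblast call was lost under 6, among them leaving out sample 2, 4, 6, 13 or 15 (r to -0.47), and the housekeeping call without sample 3 or 4 (r to -0.52). The 5 calls here and the other 7 fell to 6 in all without sample 3 and to 5 without sample 4.

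**Figure D3:**
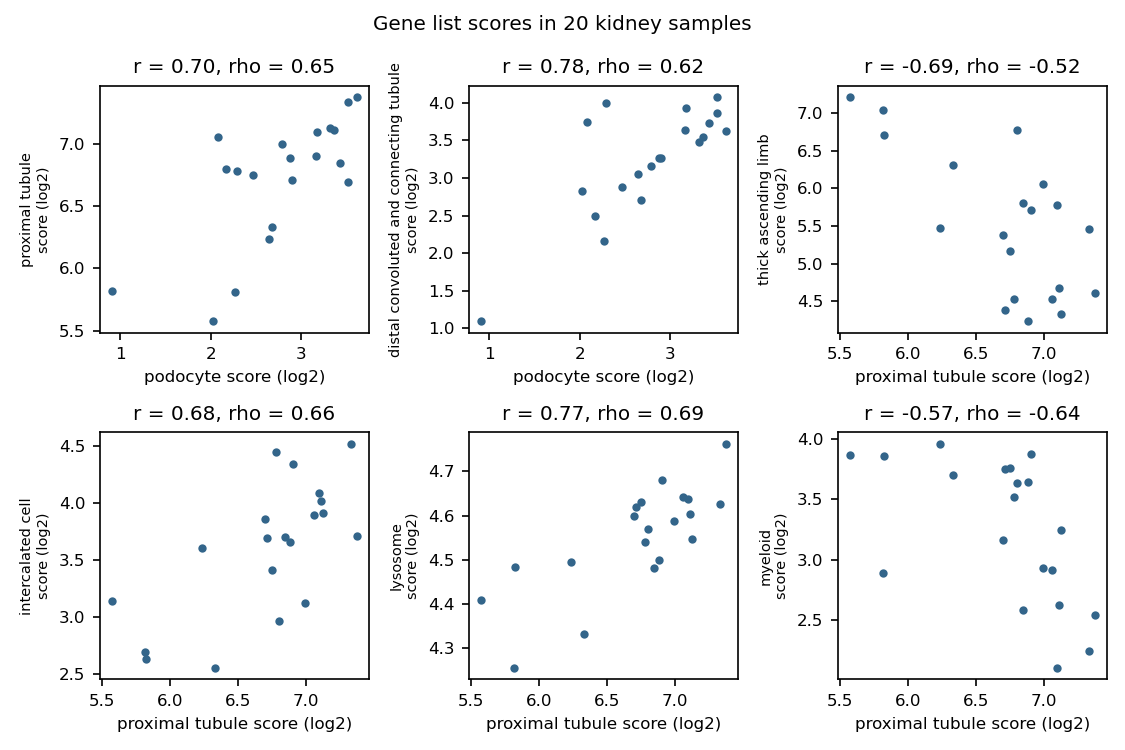
Scores of pairs of gene lists in 20 kidney samples (points), each axis being the mean of log2(value + 1) over a list's genes, with Pearson's r and Spearman's rho above each panel. Podocyte and proximal tubule scores have r = 0.70, and proximal tubule and thick ascending limb scores have r = -0.69.

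The number of genes above 0 was set against the 30 list scores. By Pearson's r, 0 of 30 lists were called after adjustment with permutation tests, and 5 had an unadjusted p under 0.05. By rank, the mesangial and mural list was called (rho = 0.69, permutation p = 0.00107, adjusted p = 0.0321 over 30 lists; r = 0.52, permutation p = 0.0214, adjusted p = 0.214). The proximal tubule score had r = -0.49 (permutation p = 0.0285, adjusted p = 0.214 over 30 lists) and rho = -0.44 (permutation p = 0.0532, adjusted p = 0.252). The largest r was that of the lysosome list (r = -0.61, permutation p = 0.00471, adjusted p = 0.141 over 30 lists; rho = -0.34, permutation p = 0.144, adjusted p = 0.361), which was -0.21 without the 2 farthest samples. The fibroblast list had r = 0.54 (permutation p = 0.0126, adjusted p = 0.189) and rho = 0.63 (permutation p = 0.00434, adjusted p = 0.0651), and the erythroid list r = 0.46 (permutation p = 0.0437, adjusted p = 0.262) and rho = 0.43 (permutation p = 0.0589, adjusted p = 0.252). Given the number of genes above 0, a test chosen after seeing the data, the proximal tubule and lysosome scores had a partial r of 0.69 (permutation p = 5.1e-04, adjusted p = 0.0190 over 57 pairs) and by ranks of 0.60 (permutation p = 0.00599, adjusted p = 0.154). Of the 12 called pairs, 6 were called again by this partial r and 0 by ranks, with permutation p under 0.05 by r in 15 of 57 pairs. The 6 lost were the podocyte pairs with intercalated cells and with genes at kidney function loci, and the proximal tubule pairs with principal cells, myeloid, fibroblast and housekeeping genes. All 12 kept their sign. The planned measure, genes with a value of at least 1, differed by 1 gene between samples and its test is void.

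By the SD of single genes, immediate early genes, globins and part of the cell type marker lists led the variation between samples. Among the 500 most variable of 11931 genes were 9 of 10 immediate early genes in the background (0.419 expected by chance, Fisher's exact test, adjusted p = 1.04e-10 over the lists), among them FOSB, EGR1, FOS and ATF3. They were joined by 7 of 11 podocyte genes (adjusted p = 9.0e-07), 5 of 7 thick ascending limb genes (adjusted p = 2.4e-05), 3 of 3 globin genes (adjusted p = 3.54e-04) and 3 of 5 distal convoluted tubule genes (adjusted p = 0.00199). Each of the myeloid and the mesangial lists had 5 of 10 genes there (adjusted p = 1.56e-04). The tubular injury list had 4 of 7 (adjusted p = 4.0e-04), the fibroblast and complement lists 4 of 9 each (adjusted p = 0.00105), the proximal tubule list 4 of 15 (adjusted p = 0.00758) and the intercalated cell list 3 of 8 (adjusted p = 0.00846). In all, 12 of 30 lists were called, and 15 had an unadjusted p under 0.05. Marker lists not called by this test were the endothelial (2 of 10 genes, adjusted p = 0.108), principal cell (1 of 6, adjusted p = 0.365) and parietal epithelial (0 of 5) lists. The lymphocyte, urothelium and adrenal cortex lists, with few genes in the background, were also not called. The list of kidney function loci had 3 of 16 genes there, UMOD, STC1 and SLC34A1, and was not called (adjusted p = 0.0608). The mesangial call was lost without sample 2 (2 genes, adjusted p = 0.108), the intercalated call without sample 3 (2 genes, adjusted p = 0.0760), the fibroblast call without sample 8 (1 gene, adjusted p = 0.515) and the complement call without sample 10 (2 genes, adjusted p = 0.0941). The fibroblast and tubular injury calls were also lost among the top 200 genes and with a pseudocount of 0.1, and the intercalated and complement calls among the top 200.

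The most variable gene was FOSB, a subunit of the AP-1 transcription factor (chromosome 19, 45971253 to 45978437), with a log2 SD of 2.18. Also among the most variable were HBB (SD 1.74), ALB, serum albumin (1.73; median 99.2, range 1.72 to 473), and FGB, the fibrinogen beta chain (1.68; median 2.41, range 0.287 to 83.1). They were followed by SLC12A3 (1.59), the mucin gene MUC13 (1.55), MIR3189 (1.53), CPNE6 (1.52), EGR1 (1.53), GC, which encodes the vitamin D binding protein (1.49), FOS (median 48.0, range 4.63 to 168), the muscle filament gene DES (1.48), the metallothionein gene MT1A (1.46) and AOC1, the diamine oxidase (1.49). MIR3189 lies inside GDF15 (median 36.6, range 12.2 to 231), so its values can be those of GDF15 reads, and FOSB lies within the span of ERCC1 on the other strand, which the libraries do not tell apart. The ERCC1 value itself varied little, from 3.94 to 6.93. MT1A belongs to a family of near-identical genes, and its value is uncertain for that reason.

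The order of genes by level was similar in all samples. Spearman correlations across 24267 genes between pairs of samples lay between 0.902 (samples 4 and 11) and 0.961 (samples 8 and 15), with a median of 0.940, and 0 pairs of files held identical values. These correlations are across genes, which are not independent replicates. Principal components of the log2 values took 26.9%, 21.0% and 9.21% of the variance. The sign of each was set to go with the podocyte score. The first had its largest r with the monogenic kidney disease (-0.87), TGF-beta (-0.84) and thick ascending limb (-0.83) scores. Its r was -0.49 with the immediate early score (permutation adjusted p = 0.108) and 0.10 with the erythroid score (permutation adjusted p = 0.906).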

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

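Leaving out samples and testing all pairs of lists were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because there was 1 group. The share of the total was 69.2% with 50 genes in place of 53.2% with 10, by its construction. The number of called relations was 12, lay between 10 and 12 under the alternatives chosen beforehand, and lay between 5 and 14 with 1 sample left out, 6 without sample 3 and 5 without sample 4. Adjusted over all 435 pairs, 8 of the 12 were kept. The calls of podocytes with the proximal tubule, and of the proximal tubule with the distal convoluted tubule, intercalated cells and lysosome, were kept under all 25 alternatives run. The proximal tubule relation with the myeloid list was lost under 15 of 25 alternatives, 12 of them a left-out sample (1, 2, 3, 4, 6, 8, 9, 11, 13, 15, 17 or 18; r to -0.51). That with principal cells was lost under 11 (samples 1, 2, 3, 4, 6, 13, 17 or 18; r to -0.40), with fibroblasts under 6 (samples 2, 4, 6, 13 or 15; r to -0.47), with housekeeping genes under 2 (samples 3 or 4; r to -0.52) and with the thick ascending limb under 1. The podocyte relation with genes at kidney function loci was lost under 11 (samples 1, 2, 3, 4, 6, 8, 15, 17 or 18; r to 0.50), with intercalated cells under 5 (samples 3, 4, 15 or 17; r to 0.49) and with the distal convoluted tubule under 1. The cause was not tested. With z-scores the proximal tubule list and genes at kidney function loci were called (r = 0.67, permutation adjusted p = 0.0138 over 57 pairs), as were podocytes and hypoxia (r = -0.60, permutation adjusted p = 0.0286). With the planned score neither pair was called. The first had r = 0.29 (permutation p = 0.210, adjusted p = 0.351 over 57 pairs) and rho = 0.13 (permutation p = 0.573, adjusted p = 0.641). The second had r = -0.47 (permutation p = 0.0377, adjusted p = 0.119) and rho = -0.48 (permutation p = 0.0328, adjusted p = 0.115). Podocytes with the myeloid list were called without sample 5, 10, 11, 16 or 19, with the thick ascending limb without sample 11 and with the endocytosis list without sample 19, and the proximal tubule with the endocytosis list without sample 5. No called relation changed sign. The number of lists enriched among variable genes was 12, between 9 and 16 under the alternatives chosen beforehand and between 11 and 12 with 1 sample left out. Among the top 200 genes 4 of the 12 calls were lost, those of intercalated cells, fibroblasts, tubular injury and complement, and the list of kidney function loci was gained, which makes 9. With a pseudocount of 0.1 the fibroblast call (1 gene, adjusted p = 0.546) and the tubular injury call (2 genes, adjusted p = 0.0773) were lost. Among the top 1000 genes the endothelial, principal cell and hypoxia lists were gained. The filter on values above 0 gained the endothelial, hypoxia, TGF-beta and kidney function loci lists. Without the trend correction the principal cell and kidney function loci lists were gained, and without sample 3 the endothelial list. The number of lists with a range over 1 log2 unit was 18, and 20 with a pseudocount of 0.1 or with list medians. Depth is unknown, so values near 0 cannot be read as absence.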

Other observations

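Over all 435 pairs of lists, a family chosen after seeing the data, 45 were called, 38 positive and 7 negative. The distal convoluted tubule and intercalated cell scores had r = 0.87 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.00217 over 435 pairs) and rho = 0.92 (permutation p = 1e-05, adjusted p = 0.00217). The fatty acid oxidation and endocytosis receptor scores had r = 0.84 (permutation p = 2e-05, adjusted p = 0.00217 over 435 pairs) and rho = 0.85 (permutation p = 1e-05, adjusted p = 0.00217). The fibroblast and complement scores had r = 0.83 (permutation p = 1e-05, adjusted p = 0.00217 over 435 pairs) and rho = 0.85 (permutation p = 2e-05, adjusted p = 0.00217). The myeloid score fell as the endocytosis receptor score rose (r = -0.77, permutation p = 1e-04, adjusted p = 0.00725 over 435 pairs; rho = -0.81, permutation p = 5e-05, adjusted p = 0.00435). Without the 2 farthest samples these r were 0.88, 0.81, 0.87 and -0.73.

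Of the tests that follow, those on the number of genes detected, the glomerular endothelium, hypoxia and the vitamin D enzymes, and those on the single genes of the hypoxia, cytokine, glucocorticoid, mesangial and parietal lists, were chosen after values that bear on the result had been seen, and the use of intervals to read the tests was added after their values were seen. All patterns were found in these samples, and the design names no biological explanation, since there is 1 group. The biological explanations weighed below rest on relations across the samples, not on a comparison of groups. In all, 11 tests with a p form the adjusted family, over r and over rho each. Percentiles among matched random sets describe a list and are not tests across samples. The random sets were matched on mean expression only. Genes of the same list can move together, which makes an extreme median more frequent than the percentile states.

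Podocyte and proximal tubule scores varied together. Random pairs of lists matched on abundance and size reached as high an r in 1.8% of 10000 draws. This cannot decide on a shift of all genes of like abundance, since the common distribution of values leaves little room for one. The random lists were also not matched on their spread between samples. The number of genes detected stays open, since given it the partial r was 0.67 (permutation p = 0.00365, adjusted p = 0.01004 over 11 tests) with a 95% interval from 0.303 to 0.860, and by ranks it was 0.50 (permutation p = 0.0275, adjusted p = 0.0432 over 11 tests). Adjusted over the larger family of list pairs in the Results, the permutation p was 0.0347 for the partial r and 0.173 by ranks. The rank test thus did not pass in that family. Without sample 3 the partial r was 0.41 (permutation p = 0.0805) and r itself was 0.62. Samples may also differ in how much cortex and medulla they hold, a hypothesis. Of 7 measured genes of the medulla and straight proximal tubule, 6 had a negative rho with the podocyte score, and their median of -0.33 lay at percentile 1.4 of matched random sets, with CRYAB at 46.8 and AKR1B1 at 18.1 as the most abundant. No test across samples was made for this list.

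Podocyte genes varied several-fold, with a fold range of the score of 6.51, and of 3.02 without sample 3. Whole glomeruli carried in differing amounts stay open as an explanation. The 5 glomerular endothelium genes had a median rho of 0.66 with the podocyte score (percentile 100 among matched random sets), but the mesangial and mural genes, 7 of 10 negative, had a median of -0.37 (percentile 0.19) and the 5 parietal epithelial genes 0.0075. The mesangial and mural list also holds genes of vessel walls outside the glomerulus, and the parietal epithelial score rose with the tubular injury score (r = 0.76). The most abundant glomerular endothelium genes were CRHBP at 7.33 and EHD3 at 4.00, and EHD3 and SOST are also in the endothelial list. The dissection in the labels would part glomeruli from tubules, but the labels do not say which part a file holds. The number of genes above 0 had r = -0.29 with the podocyte score (permutation p = 0.212, adjusted p = 0.259 over 11 tests) and rho = -0.46 (permutation p = 0.0442, adjusted p = 0.0608), and the interval of r from -0.649 to 0.175 leaves it open.

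Immediate early genes varied several-fold. Their score rose with the hypoxia score (r = 0.64, permutation p = 0.00215, adjusted p = 0.00788 over 11 tests; rho = 0.63, permutation p = 0.00359, adjusted p = 0.00790), but the hypoxia genes as a set were not beyond matched random sets. Of 10 genes, 6 had a positive rho and 4 a negative one, with a median of 0.088 (percentile 88.5). The immediate early score also rose with 7 cytokine and NF-kappaB target genes, with NFKBIA at 42.2 and ICAM1 at 3.13 (r = 0.75, permutation p = 4e-05, adjusted p = 4.4e-04 over 11 tests; rho = 0.76, permutation p = 1.7e-04, adjusted p = 0.00187), all 7 with a positive rho and a median of 0.70 (percentile 100). Inflammatory signalling may contribute, as a hypothesis, but this relation cannot tell it from another stimulus that raises both lists. Oxygen shortage before fixation also stays open. The number of genes above 0 had r = 0.26 (permutation p = 0.266, adjusted p = 0.292 over 11 tests) with an interval from -0.203 to 0.632 and rho = 0.19 (permutation p = 0.428, adjusted p = 0.470), and stays open.

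FKBP5, a gene induced by glucocorticoids, ranged from 2.32 to 55.3 and rose with 4 other glucocorticoid response genes (r = 0.74, permutation p = 1.2e-04, adjusted p = 6.6e-04 over 11 tests; rho = 0.66, permutation p = 0.00183, adjusted p = 0.00503), all 4 with a positive rho and a median of 0.54 (percentile 100), so differing glucocorticoid exposure may contribute, as a hypothesis. These 4 genes also had a positive rho with the immediate early score (median 0.44) and a negative one with the proximal tubule score (median -0.36). Their relation with FKBP5 was not tested apart from those scores. CYP27B1 and CYP24A1, which activate and inactivate vitamin D, showed no opposite movement past the test (rho = -0.13, permutation p = 0.594, adjusted p = 0.594 over 11 tests; r = -0.020, permutation p = 0.935, adjusted p = 0.935). ALB had r = 0.37 with 6 other plasma protein genes (permutation p = 0.105, adjusted p = 0.165 over 11 tests; rho = 0.38, permutation p = 0.0963, adjusted p = 0.118). FGB had r = 0.55 with them (permutation p = 0.00909, adjusted p = 0.0167 over 11 tests; rho = 0.66, permutation p = 0.00158, adjusted p = 0.00503). MT1A had r = 0.35 with 5 other metallothionein genes (permutation p = 0.130, adjusted p = 0.179 over 11 tests; rho = 0.53, permutation p = 0.0187, adjusted p = 0.0342), and MT1M had r = 0.58 (permutation p = 0.00634, adjusted p = 0.0139; rho = 0.69, permutation p = 0.00101, adjusted p = 0.00503). Reads of these near-identical genes can be split between them.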
